A study of Caenorhabditis elegans with 2 samples.

How the data were processed

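Chromatin immunoprecipitation with sequencing (ChIP-seq) had been run on whole Caenorhabditis elegans hermaphrodites carrying ZFP-2, a C2H2 zinc finger protein, fused at its C terminus to GFP and FLAG. The labels describe strain OP534, an unc-119 mutant with an integrated transgene, collected as L4 larvae 52 hours after release from L1 arrest. An anti-GFP antibody was used after sonication. The labels number the libraries as biological replicates 1 and 2 of a single group, so the design holds no contrast between conditions and no paired comparison. A control data set was linked to both replicates and was not used here.

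The deposited files were peak lists without a header. Per the series' description file, the submitters supplied 1 list per replicate, 1 list from the pooled replicates and 1 thresholded list by irreproducible discovery rate (IDR), each on the ce10 and ce11 builds. The per-replicate and pooled lists include background calls that served as the input of IDR. The signal of a peak is the authors' value and was used only to rank and describe peaks within a list. The deposited −log10 q-value took a single value, 1.96, in the thresholded ce11 list and was therefore not used for ranking. The summit was read from the deposited offset in each peak. The aligner, the peak caller and the IDR threshold are not given in the sources used here. Read depth is unknown, so no interval based on reads is given. Intervals for shares are exact Clopper-Pearson 95% intervals that treat peaks or genes as independent, which neighbouring peaks and genes are not.

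The thresholded ce11 list was the main set. All of its 660 peaks stood in the pooled list with the same position and signal, and they were that list's 660 strongest. It therefore carries no separate error between replicates, and replicate lists were compared through their 660 strongest peaks. Coordinates are 1-based on ce11, which has the sequence of WBcel235, and annotation came from Ensembl release 115. No peak ran past a chromosome end. Lists on ce10 were used for counts and signal, and no coordinate was converted. Mitochondrial peaks were counted apart.

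A promoter window ran from 1000 bp upstream to 200 bp downstream of each of 29784 annotated 5′ ends of 19973 nuclear protein-coding genes. A gene is called bound when a summit lay in its window. As 1 summit can count for several genes, it can also count for several lists or families. Shares of summits were compared with 1000 random placements within their chromosomes by a two-sided permutation test whose smallest p is 0.001. Chromosome counts and the share in the middle of the autosomes were tested with exact two-sided binomial tests. Gene lists, symbol families with at least 10 members, divergent promoters and 6-base words were tested with two-sided Fisher's exact tests. Benjamini-Hochberg adjustment was applied within each family of tests, at a threshold of 0.05. Words were counted on both strands together in sequences centred on the summit and on positions 500 bp to either side of it. Noncoding genes counted as near within 250 bp, and summits matched between lists within 100 bp.

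The gene lists, planned tests, alternatives and the rule for named genes were fixed before the data were examined. The comparisons of X with autosomes, in promoter share and in bound tRNA genes, were not among the planned tests. Named genes are those with a promoter window holding 1 of the 20 strongest summits (otherwise the gene body or nearest 5′ end), zfp-2 and unc-119, up to 4 bound members of each list, up to 3 members of each family past the threshold, and the 10 words with the lowest p. Alternatives covered a stricter signal threshold, each replicate's own list, other windows, distances, backgrounds, denominators and rules that tie peaks to genes. Alternatives that left out summits near tRNA genes or used shuffled sequences were chosen after seeing the data.

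The statistics were tested on simulated data first. In 20 random sets of 642 summits, the promoter test called 1 set, and no gene list and no word was called. These summits were drawn evenly along chromosomes, without the promoter preference or base composition of the real ones. The sets therefore cannot show how often lists or words are called because of those features. With 30 summits planted at ribosomal protein genes the list was called in 20 of 20 sets, and a word planted in 20% of sequences was called in 20 of 20. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.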

Results

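Binding of GFP-tagged ZFP-2 was mapped by ChIP-seq in L4 hermaphrodites, in 1 group of 2 biological replicates. The replicate lists held 18200 and 17770 peaks with background calls included, the pooled list 14658, and the thresholded list 660 on ce11. Of these 660 peaks, 642 were nuclear and 18 mitochondrial. Peak width had a median of 436 bp, with a range of 109 to 1228 bp. The authors' signal ranged from 83.8 to 8713 with a median of 117. The ce10 version of the thresholded list held 871 peaks, and at equal rank its signals differed from those on ce11 by at most 1.10%. Read depth is unknown.

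The first question was which sites stood out. The strongest nuclear peak lay on chromosome I from 9625771 to 9626388, with signal 4889, between hsr-9, the worm homologue of the DNA damage response protein 53BP1, and rps-19, a protein of the small ribosomal subunit. Its summit lay 162 bp from the 5′ end of hsr-9. The next stood on II from 8561150 to 8561702 at iff-2, a translation factor of the eIF5A family, and F54C9.14, with signal 4206. A peak on IV from 13240391 to 13240939 had signal 4010 and lay in the windows of rpl-12, a large-subunit ribosomal protein, and lin-54, a DNA-binding member of the DREAM complex. On X, the strongest peak ran from 5841006 to 5841603 in the promoter window of puf-9, which encodes a Pumilio-family RNA-binding protein, with signal 3662. Peaks at rps-12 and ska-3 on III (signal 3535) and at rps-15 and F36A2.9 on I (signal 3311) came next. The peak of sqd-1, an RNA-binding protein gene on IV, had signal 3098.

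Of the 20 strongest peaks, 13 were nuclear, and all 13 had their summits in promoter windows. The remaining nuclear ones were at attf-2 and F09G2.2 (signal 2476), at ant-1.1, an adenine nucleotide translocator, with abcf-2 and T27E9.2 (signal 2458), at the alpha-tubulin gene tba-2 (signal 2381), at vig-1 (signal 2367), at egl-30, a Gq alpha subunit, with C53H9.4 (signal 2112), and at the prefoldin gene pfd-1 with F01G4.6 (signal 1920). The other 7 were mitochondrial, with summits in WBGene00010967 (signal 8713), WBGene00000829 (signal 5403), ND1 (signal 3064), COX3 (signal 2671), WBGene00010964 (2 peaks) and a ribosomal RNA gene. As the control was not used, these mitochondrial peaks cannot be told apart from background. Signal fell steeply: 25 nuclear peaks were above 1000 and 604 were at or below 500.

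The strongest sites were shared by both replicates. The 12 strongest nuclear peaks were among the 12 strongest nuclear peaks of each replicate. Of the nuclear peaks among the 660 strongest of replicate 1, 445 of 642 (69.3%, 95% interval 65.6 to 72.9) overlapped 1 of the 660 strongest of replicate 2 by at least 1 bp. Random placement gave 0.617% on average (permutation p = 0.001, the smallest possible). Of the nuclear thresholded peaks, 607 had a summit within 100 bp in both full replicate lists, background calls included. Across these, Spearman's rho of signal was 0.657 and Pearson's r of log2 signal was 0.91. Thresholded peaks are the strongest by pooled signal, so weaker calls do not enter. These correlations are across peaks, which are not independent replicates.

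**Figure D1:**
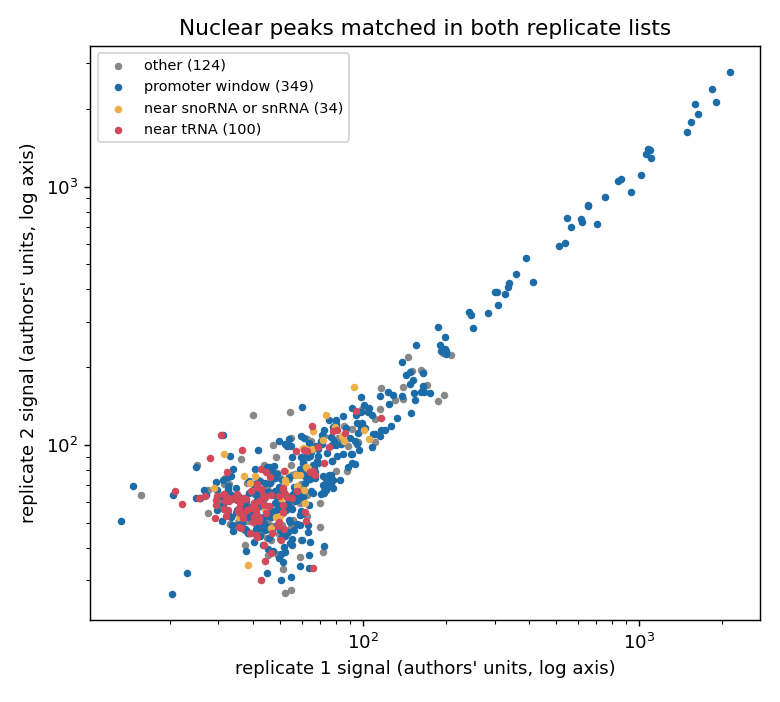
Signal of each matched nuclear peak in replicate 1 (x axis) and replicate 2 (y axis), in the authors' units on log axes, with 1 point per peak coloured by site class. The 607 points give a rho of 0.657, and the points of highest signal are promoter peaks.

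Where did ZFP-2 sit relative to genes? Promoter windows held 396 of the 642 nuclear summits (61.7%, 95% interval 57.8 to 65.5), against 25.6% ± 1.76 (SD over 1000 random placements, permutation p = 0.001). Each summit was counted once, in the first of promoter window, exon, intron, noncoding gene and intergenic sequence that held it. Random placements were counted likewise. Outside promoter windows, exons held 1.87% against 21.7% at random, and introns 96 of 642 summits against 28.0% (adjusted permutation p = 0.00125 for each). The exon share was 2.96% in replicate 1 alone and 3.40% in replicate 2 alone, with the call kept. Intergenic sequence held 16.2% against 21.6% (adjusted permutation p = 0.003) and noncoding genes 5.30% against 3.13% (adjusted p = 0.00125). These last 2 calls were lost among the 330 strongest peaks. Stronger peaks lay in promoters more often, with 213 of the 321 stronger nuclear summits (66.4%) against 183 of the 321 weaker (Fisher's exact test, odds ratio 1.49, p = 0.0185).

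Divergent gene pairs were bound more often. Of 5′ ends with an oppositely oriented 5′ end within 2000 bp upstream, 498 of 7539 (6.61%) had a summit in the window, against 285 of 22245 others (1.28%; Fisher's exact test, odds ratio 5.45, p = 4.76e-116). A summit between divergent genes counts for both, so part of this ratio is built in. Different 5′ ends of 1 gene were also counted apart, so this p is too small. With each peak given only to its nearest 5′ end, the odds ratio was 1.92 (exact p = 3.32e-12).

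Which genes were bound? Summits lay in the promoter windows of 558 protein-coding genes, 2.79% of all. Ribosomal protein genes stood far above this, with 37 of 81 bound (45.7%, 95% interval 34.6 to 57.1; Fisher's exact test, odds ratio 31.3, adjusted p = 1.15e-34). With each peak given only to its nearest 5′ end, 22 of 81 (27.2%) were bound and the odds ratio was 15.3, and among the 330 strongest peaks it was 48.2. The strongest were rps-19, rpl-12, rps-12 and rps-15. Both subunits were represented, with 22 of 47 rpl genes and 15 of 31 rps genes bound. After the leading gene rpl-12, the rpl peaks of highest signal were those of rpl-11.2 (1485) and rpl-36 (1266).

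Genes of mitochondrial respiration encoded in the nucleus followed, with 11 of 36 bound (30.6%, odds ratio 15.6, adjusted exact p = 2.69e-08). The odds ratio was 10.3 in replicate 2 alone, with 8 of 36 bound, and 10.3 among the 330 strongest peaks, with 5 of 36 bound. The bound genes included the ATP synthase gene atp-1 (signal 1364) and the cytochrome c oxidase genes cox-5A (352), cox-5B (253) and cox-6B (215). Heat shock and stress genes had 8 of 41 bound (odds ratio 8.54, adjusted exact p = 8.60e-05; odds ratio 5.51 by nearest 5′ end), led by the chaperone genes hsp-60, hsp-1, hsp-110 and hsp-3 with signals from 289 down to 174. Splicing and RNA processing genes had 12 of 75 bound (odds ratio 6.75, adjusted exact p = 8.10e-06), among them prp-8, rsp-7, snr-1 and rsp-1. In this list rsp-1 and rsp-2 had the same peak signal (120), as had rsp-5 and snr-3 (98.9). By nearest 5′ end 8 of 75 were bound (odds ratio 4.76), and among the 330 strongest peaks 5 of 75 (odds ratio 4.54), with the call kept. Translation factors and tRNA synthetases had 9 of 69 bound (odds ratio 5.29, adjusted exact p = 0.00057), with the elongation factor genes eef-1A.1 (signal 1499), eef-2 (signal 1100) and eef-1G (signal 238) and the initiation factor gene eif-3.C (signal 215) strongest. Against genes with given symbols only, the odds ratio of this list was 3.77, with the call kept.

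The 3 other lists past the threshold rested on few genes. The vulval induction and synMuv list had 5 of 34 bound (adjusted exact p = 0.00912), with lin-54, lin-53, lin-35 and lin-9 strongest. The lin-54 peak is the one shared with rpl-12, and the call was lost when each peak was given to its nearest 5′ end (adjusted exact p = 0.131). Heterochronic and molting genes had 4 of 22 bound (lin-46, myrf-2, lin-66 and myrf-1, adjusted exact p = 0.00971), a call lost in replicate 1 alone (adjusted exact p = 0.322) and among the 330 strongest peaks (adjusted exact p = 0.675). The proteasome list had 4 of 33 bound (pbs-1, rpn-3, rpn-11 and pbs-2, adjusted exact p = 0.0373), a call lost against genes with given symbols only (adjusted exact p = 0.0963). In this list rpn-3 had the same peak signal as hsp-110 (182), and pbs-2 the same as eif-6 (115), genes of other lists past the threshold.

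No other list passed the threshold. Chromatin and dosage compensation genes had 4 of 49 bound (htz-1, cbp-1, lin-35 and zfp-3, adjusted exact p = 0.122). This list passed under 5 of the alternatives. In those by Fisher's exact test the adjusted p ran from 0.0232 to 0.0308. The other was a permutation test against summits shifted along their chromosomes (adjusted p = 0.0153). Shifted summits lose the promoter preference of all peaks, so that test does not speak for this list in particular. Cell cycle genes had 2 of 39 bound (pcn-1 and cye-1). Collagens and cuticle genes had 3 of 172 bound (col-38, col-185 and col-63), and nuclear hormone receptors 4 of 274 (nhr-142, nhr-47, nhr-255 and nhr-40). Histones (his-37), muscle (act-2), neurons (egl-21), neuropeptides (ins-39) and homeobox factors (ceh-38) had 1 bound member each. Germ line genes had 0 of 38 bound, which allows a share of up to 7.89%, intestinal genes 0 of 37 (up to 8.11%), Wnt, Notch and TGF-beta genes 0 of 43 (up to 6.98%), major sperm proteins 0 of 31 (up to 9.68%) and hypodermal genes 0 of 23 (up to 13.0%). These one-sided limits take 3 counts of the total as the most that a count of 0 allows, and cover counting error only.

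**Figure D2:**
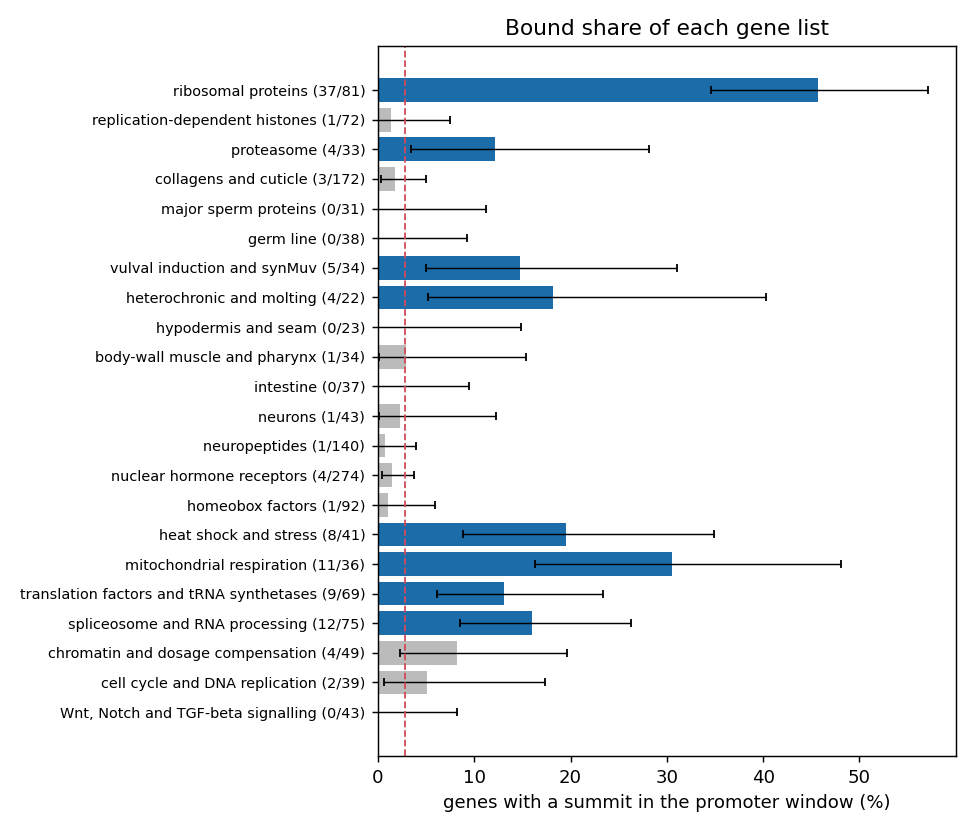
Share of each gene list with a summit in the promoter window (x axis, percent), with exact 95% intervals as error bars and bound and total members in brackets. Blue bars have an adjusted p under the threshold, and the dashed line marks the 2.79% of all protein-coding genes.

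An unselected scan of symbol families, against all other protein-coding genes with or without a given symbol, gave 9 past the threshold (Fisher's exact test). Besides rpl and rps these were lin (8 of 47, led by lin-54, lin-53 and lin-35), dnj chaperones (6 of 29, dnj-13, dnj-9 and dnj-28), sec genes of protein secretion (5 of 19, sec-61.G, sec-61.B and sec-15), hsp (5 of 22, hsp-60, hsp-1 and hsp-110), cox (4 of 15, cox-5A, cox-5B and cox-6B), rab GTPases (4 of 20, rab-18, rab-7 and rab-11.1) and vha proton pump subunits (4 of 20, vha-8, vha-12 and vha-13). Ribosomal protein peaks also entered other families. The lin-54 peak is the one shared with rpl-12, rab-11.1 had the same peak signal as rpl-7 (90.9), and sec-61.A the same as rps-18 (99.0). The rab call was lost with either replicate alone (adjusted exact p = 0.817 in replicate 1 and 0.180 in replicate 2), and the vha call in replicate 2 alone (adjusted exact p = 0.643). Among the 330 strongest peaks the dnj, sec, rab and vha calls were lost (adjusted exact p = 0.773, 0.0671, 0.563 and 1). In the window of 500 bp up and 100 bp down, where 6 families passed, the cox, rab and vha calls were lost (adjusted exact p = 0.0900, 1 and 0.182).

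Small RNA genes formed another class of peak sites. Whether these peaks reflect binding or capture by the antibody was not tested. No immunoprecipitation from untagged animals was used here. Summits lay near tRNA genes in 105 of 642 cases (16.4%, 95% interval 13.6 to 19.4) against 0.341% at random, a 48.0-fold excess (adjusted permutation p = 0.0015). The share was 8.97% among the 330 strongest peaks. Of the 105, 29 also lay in a promoter window. Near snoRNA genes there were 48 summits (7.48% against 0.213%) and near snRNA genes 15 (2.34% against 0.0715%), with the same adjusted p, the last 3.53% among the 330 strongest. Counted by gene, 118 of 612 tRNA genes (19.3%), 48 of 346 snoRNA genes (13.9%) and 9 snRNA genes (6.98% of that class) had a summit nearby. The 15 summits near snRNA genes thus lay at 9 genes, some of which had more than 1, and are not 15 independent sites. piRNA loci were depleted (0.779% against 3.43%, adjusted permutation p = 0.0015). Chromosome IV carries 14714 of the 15363 piRNA genes, so the comparison rests mainly on that chromosome. The piRNA share was 1.40% in replicate 1 alone, with the call kept, and 1.60% among the 330 strongest peaks, where it was lost (adjusted permutation p = 0.102). MicroRNA precursors had 4 summits (adjusted permutation p = 0.018), a call lost in replicate 1 alone (adjusted permutation p = 0.316) and among the 330 strongest peaks (adjusted permutation p = 0.452). Nuclear rRNA genes had 0 summits.

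Peaks were unevenly spread over chromosomes. Chromosome V held 72 of 642 peaks, 0.537 times its share by length (exact binomial test, adjusted p = 8.94e-10). Chromosomes I and III held 1.30 times theirs (exact binomial test, adjusted p = 0.00571 for each), while II, IV and X did not pass. Measured against its share of genes in place of length, X held 1.49 times its share and passed (exact binomial test, adjusted p = 8.69e-06). On autosomes, 199 of 511 peaks (38.9%) lay in the central one of 3 equal parts of their chromosome (exact binomial p = 0.00852), close to the 38.1% of genes there (exact p = 0.716).

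In comparisons that were not planned in advance, the X chromosome differed in the kind of site. Promoter windows held 51 of its 131 summits (38.9%) against 345 of 511 on autosomes (67.5%; Fisher's exact test, odds ratio 0.307, p = 3.43e-09). tRNA genes accounted for 58 of the X summits. X carries 276 of the 612 tRNA genes, of which 64 (23.2%) had a summit nearby against 54 of 336 on autosomes (16.1%; Fisher's exact test, p = 0.0305). Without summits near tRNA genes, X held 73 peaks, 0.769 times its share by length (exact binomial test, adjusted p = 0.019). That was 13.6% of the peaks left, close to the 13.7% of genes on X, a comparison that was not tested.

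**Figure D3:**
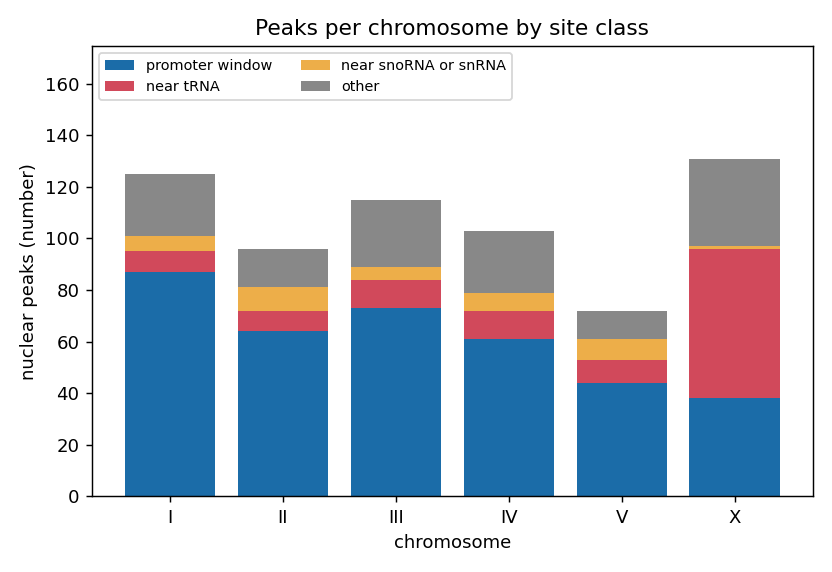
Number of nuclear peaks (y axis) on each chromosome (x axis), stacked by site class, where a summit near a tRNA gene is counted there first. The X bar holds 58 summits near tRNA genes, more than the 8 to 11 on any autosome.

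Sequence at the summits was richer in G and C, 49.4% ± 8.01 (SD over 642 summits) against 37.1% ± 8.87 in the flanks. Of the 6-base words tested, 507 were found more often and 392 less often at summits. ACGCAG led, in 113 of 642 summits (17.6%) against 21 of 1284 flanks (1.64%; Fisher's exact test, adjusted p = 2.59e-33). GACGCA and AGACGC, which overlap it in part, were each in 103 of 642 summits. ACGCGC, ACACGC, GAGCGC, CGAGAG and GCGAGA were in 12.5 to 17.9%. AAAAAT fell from 44.9% of flanks to 19.9% of summits, and TAAAAA from 30.1% to 10.3%. Against shuffles of the summit sequences that keep dinucleotide counts, chosen after seeing the data, 137 words were higher and 147 lower. The odds ratio of ACGCAG fell from 12.8 to 2.94, and those of all 8 enriched leading words to between 1.49 and 3.04. ACGCGC and TAAAAA were then no longer past the threshold (adjusted exact p = 0.0661 and 0.971), and the direction turned for AAAAAT and TAAAAA.

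The tagged gene itself was checked because the transgene adds copies of its locus. zfp-2 lies on II from 9557650 to 9559516 on the plus strand, and no thresholded peak lay in the gene or within 20 kb. Of 10000 random windows of that length on II, 78.8% held none either. The pooled list also had 0 peaks there, as few as in 5.20% of random windows. unc-119, the marker mutated in the strain, lies on III from 10902641 to 10908935 and had 0 thresholded and 10 pooled peaks within 20 kb.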

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

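Both results here lie outside the comparisons of the report, and both were chosen after the data were seen. The mitochondrial genome held 18 thresholded peaks, covering 41.4% of its 13794 bp, with signal from 240 to 8713. The replicate 1 list held 18 mitochondrial peaks and the replicate 2 list 12. Whether these peaks reflect binding or background was not tested, as the control was not used.

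Pooled peaks ranked 661 to 1320, just below the thresholded set, had summits in promoter windows in 351 of 660 cases (53.2%) against 25.8% at random (permutation p = 0.001, the smallest possible). The 660 weakest pooled peaks, ranked 13999 to 14658, had 26.8% against 26.2% (permutation p = 0.757).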

How the results depend on the processing

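The alternatives with summits near tRNA genes left out and with shuffled sequences were chosen after seeing the data. The 660 strongest pooled peaks are the thresholded set itself, so that alternative tests nothing and is left out of the counts here. Of 59 alternative values of the main results, 51 kept their direction and side of the threshold, or stayed within 1.5 times for counts. No paired analysis was possible because there is a single group. With 1 replicate's list in place of both, the promoter share ranged from 59.6 to 62.8%, lists past the threshold from 7 to 9 and families from 7 to 9. The promoter share ran from 49.8% in the narrowest to 72.7% in the widest window.

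The share in the middle of the autosomes was 38.9% among the 330 strongest peaks (exact binomial p = 0.0638, with fewer peaks tested) and 38.9% against the share of genes (p = 0.716, since genes are themselves more frequent there). Among the 330 strongest peaks, genomic features departing from random went from 5 to 3, noncoding classes from 5 to 3, and 6-base words from 899 to 577, with fewer peaks tested. Against dinucleotide shuffles 284 words passed. The odds ratio of AAAAAT turned to 1.80 and that of TAAAAA to 1.03, where base composition no longer separates the sets. Without summits near tRNA genes, the ratio of X peaks to length turned to 0.769. Windows of 10 and 40 kb round zfp-2 matched 88.4 and 62.7% of random windows, as their length implies. Read depth is unknown, so its effect on the weaker peaks could not be measured.

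Of 390 values for single lists, families, classes, chromosomes, words and loci, 340 kept direction and call, 20 lost their call, 6 gained 1, 2 moved and 22 turned. The 3 turned values with a call on either side are the X, AAAAAT and TAAAAA values above. The other 19 were past the threshold in neither setting. Apart from those against shifted summits, given last, their cause was not tested. Among the 330 strongest peaks they were chromosome II (1.07 times its length), X (0.998) and muscle genes (odds ratio 0). Without tRNA summits II held 1.08. With 1 replicate's list the ranges were 0.981 to 1.01 for II, 0.885 to 1.03 for IV, 0 to 1.05 for muscle, 0.824 to 1.74 for neurons and 0.910 to 1.92 for cell cycle genes. In the widest window collagens had 1.11 and muscle 0.788, in the narrowest neurons 1.10. By nearest 5′ end collagens had 1.68, and against genes with symbols muscle 0.750. Against shifted summits the ratios were 2.34 for histones, 2.26 for collagens, 1.88 for neurons, 1.96 for nuclear hormone receptors and 1.02 for homeobox factors. These ratios are bound genes over their mean number after shifting, and are not odds ratios against other genes. Shifting takes summits off promoter windows, which held 61.7% of them against 25.6% at random. A list bound at the average rate therefore lies above 1 there.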

Other observations

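The tests of the chance gap round zfp-2 and of promoter words at the X sites were chosen only after the pattern was seen, as were the long word itself and, for ribosomal protein promoters, the masked windows and the comparison with other genes. The other tests had their predictions written before their results.

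On X, 34 summits lay outside promoter windows and away from tRNA, snoRNA and snRNA genes. Of these, 10 (29.4%) held a match of at least 10 of 12 bases to TCGCGCAGGGAG, a motif known from sites that recruit the dosage compensation complex to X, against 3 of 100 such autosomal summits (Fisher's exact test, odds ratio 13.5, p = 5.73e-05). The word was chosen on these sites, so this p is too small. A perfect match lay under the peak on X from 2996999 to 2997270, in an intron of Y41G9A.17, with signal 281. The strongest, on X from 6296445 to 6296736 in an intron of mom-1, had signal 354 and TCGCGCAGGGAA. Intergenic peaks from 11094062 to 11094335 (signal 344) and from 806558 to 806786 (signal 341) held TCGCGCAGGGAC and TCGCACAGGGAG.

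At the 34 X sites, chance recurrence of words from base composition is argued against in a test that left the word open. The long word had already been chosen on the same sites, so this test is no independent support for it. CGCAGGGA and CCCTGCGC, both part of the long word, were each in 8 of the 34 sites, while in 0% of 1000 dinucleotide shuffles was any 8-base word in as many, with 5 at most. The long word was not found again in excess at weaker X sites of this kind, among pooled peaks ranked 661 to 1320. There 1 of 32 held a match, as many as in 24.2% of shuffles. Whether the X sites share the words of autosomal promoters depended on the words taken. Of 10 words that led at odd-ranked autosomal promoter summits, at least 1 was in 67.6% of the 34 sites, against 71.3% of 164 even-ranked summits (Fisher's exact test, p = 0.682), and GCGCGA, part of the long word on its other strand, was among them. With such words left out it was 58.8% against 72.0% (exact p = 0.152). Words from the even-ranked summits gave 41.2% against 74.5% of the odd-ranked (exact p = 0.000376). Words from all 329 summits gave 44.1% against 77.8% (exact p = 8.95e-05). That 77.8% is at the summits that supplied the words, so a lower share on X was favoured and this p decides nothing. This explanation therefore stays open. A hypothesis is that ZFP-2 may be found at dosage compensation recruitment sites, directly or with other proteins there. Capture of any crowded site by the antibody stays open, because no immunoprecipitation from untagged animals was used here. Binding data for dosage compensation proteins at the same sites, and another GFP-tagged factor, would separate these.

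Ribosomal protein promoters could be bound through sequence, or captured because they are strongly transcribed. From promoter summits of other genes 342 words were learned. Bound ribosomal protein promoters held 98.6 ± 14.6 of them (SD, n = 37 genes) and unbound ones 99.1 ± 14.5 (n = 44), a difference of -0.523 (permutation p = 0.878). For scale, 172 words were learned at the odd-ranked of these summits. In windows of 1201 bp round the even-ranked ones, masking the summit removed 8.20 more of them than masking a flank of equal length. The ribosomal difference with these words was -0.703 (95% interval -4.92 to 3.52, permutation p = 0.753). The words thus did not separate bound from unbound ribosomal protein promoters. As a class, however, these promoters were rich in the 342 words: 1320 unbound promoters of other genes held 81.0 ± 20.2, which is 18.1 fewer than the unbound ribosomal ones (95% interval 13.6 to 22.6). Binding through these words and capture whatever the sequence therefore both stay open. Base composition also stays open: of 309 words higher at odd-ranked summits, 16.5% passed at even-ranked summits against dinucleotide shuffles, between the limits set in advance.

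The region round zfp-2 lay in a stretch of 89400 bp on II without a pooled peak, the 9th longest of 13315 between peaks. Low mappability is argued against, since 36.4% of random stretches of that length on II had as few unique 31-base words. Chance stays open as a candidate explanation, with values on both sides of 5%. For the gene with 20 kb to either side, 5.20% of random windows held as few pooled peaks, 2.07% in replicate 1 and 1.49% in replicate 2. Stretches at least as long as the one round zfp-2 made up 2.73% of chromosome II in the pooled list, 1.80% in replicate 1 and 1.98% in replicate 2. Whether extra copies of the locus in the control DNA lowered the signal was not tested, as the control was not used here.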
